A study of Mus musculus with 8 samples.

How the data were processed

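The submitters' processing notes name FastQC, cutadapt, STAR and the mm10 mouse genome, without versions. Sorted cells were obtained, per the labels, by papain dissociation and cell sorting, and RNA libraries were made with a low-input stranded kit of the SMARTer Pico series. The deposited table holds 22553 genes and 24 value columns for 4 groups. Per the file headers, each group has footprint counts, coding length, input RNA counts, the authors' translational efficiency, footprint RPKM and RNA TPM. Counts are, per the file headers, reads over coding sequences, and the coding length is the authors' value in bases. RPKM and TPM were recomputed from the deposited counts and lengths with no difference beyond rounding. The authors' translational efficiency ratio equals the footprint share over the RNA share times a constant of 1.34, 1.34, 1.33 and 1.38 in the 4 groups.

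The labels list 8 footprint libraries, 2 per group, and the table has 1 column per group and assay. How the columns were made from the libraries is not given in the sources used here. The KO of OMP-GFP cells is tagged as OMP-ires-Cre in its genotype and described as OMP-ires-GFP, and it was taken as the OMP-GFP KO group by its description. Comparisons and alternatives had been fixed before the data were examined, with tests that assumed replicates. Since the table has 1 column per group, those tests were replaced by a description: genes at least 2-fold apart whose exact counting interval excluded 1. This description and the rule for naming genes were chosen after the structure of the table was seen.

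Counts were scaled by TMM (edgeR 4.0.16 in R 4.3.3), and genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 13479 genes for footprints and 16388 for RNA. Ratios were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9. A gene needed at least 20 counts in the pair of columns. Intervals are exact conditional binomial 95% intervals for footprints and RNA, and approximate for efficiency and for the difference of effects. A count of 0 was set to 3 counts, and the fold is then given as "at least". That wording marks the setting and is no bound of the counting interval, which can lie nearer to no difference. In the columns 3 footprints were worth 0.673, 0.990, 0.839 and 0.732 CPM, in the order Ngn1-GFP control, Ngn1-GFP KO, OMP-GFP control and OMP-GFP KO. Genes with a footprint numbered 15577, 14331, 14503 and 13235, and kept genes had median counts of 114, 71, 70 and 73. Efficiency had been foreseen only as a model over libraries, and only if input RNA columns could be matched to the samples by name. The RNA columns match the groups and not the libraries, so efficiency is given as a plain ratio without a model, a choice made after the table was seen.

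Scaling by library size alone moved median footprint ratios of OMP-GFP over Ngn1-GFP by -0.21 in controls and -0.23 in KO, and the RNA ratio of the KO pair by -0.12. It moved median efficiency ratios by -0.12 for the Ngn1-GFP KO, -0.17 for the control pair of populations and -0.11 for the KO pair. Other shifts of the median between scalings were below 0.1.

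Named genes are Mex3a, the 8 largest ratios in each direction with a mean of at least 5 CPM, up to 3 members of each list by the bound of the interval nearest 0, and for the difference of effects the 5 largest in each direction by that bound. Genes known only by a predicted or pseudogene name were counted and left unnamed. Receptors, the relatives of Mex3a and the genes shown for the RNA columns were also named after their values were seen. 29 gene lists were used: the lists reported by name in the report, with members fixed before the data were examined. Cell-type lists hold published markers, and the receptor, histone, ribosomal, mitochondrial, trace amine, vomeronasal and protocadherin lists follow symbol patterns; H13, which matches the histone pattern and is no histone, was left out. Each list median was placed among 10000 random lists matched in 40 bins of abundance, and its bootstrap interval used 2000 draws over members. Neither describes variation between animals. Symbols were matched to the RefSeq table of GRCm38.p6, where 21322 (94.5%) were found; receptor families came from its synonyms for 1083 of 1104 receptors.

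Receptor sums were compared with binomial intervals. Breadth was the number of receptors detected after 100 random thinnings to the smallest column, with the effective number taken from Shannon entropy. Matched genes for breadth were other genes of the same abundance at the same total of 3031489 footprints.

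Alternatives were DESeq2 1.42.0 size factors, library size alone, TMM without receptor, mitochondrial and ribosomal genes, no filter beyond 1 count, and at least 50 counts in 2 columns. These had been fixed for the gene comparisons, and only in part for lists, receptor sums and the agreement of effects. After the data were seen, 0.5 added to each count, at least 100 counts in the pair, removal of histones and genes with a named pseudogene, all alternatives for efficiency and receptor RNA, the remaining scalings and filters for lists, receptor sums and agreement, and receptors of families of 1 to 3 members were added.

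The steps were run on simulated counts with known changes of 2-, 4- and 8-fold. With a mean of 100 or more counts, 100% of 4-fold and 8-fold changes were called in the right direction; for 2-fold changes it was 44.8% in the Ngn1-GFP and 41.5% in the OMP-GFP comparison. Of unchanged genes 0.435% and 0.582% were called, and the intervals held the true value for 95.9% and 95.7% of genes. Of 40 unshifted lists, 38 and 39 lay between percentiles 2.5 and 97.5. The simulation held counting error alone, so it says nothing on variation between libraries. Results for a few genes are not reported here.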

Results

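Ribosome footprints, the stretches of mRNA covered by ribosomes, were sequenced together with input RNA from cells sorted out of the mouse main olfactory epithelium. Cells positive for Ngn1-GFP are neuronal precursors and immature olfactory sensory neurons, and cells positive for OMP-GFP are mature olfactory sensory neurons. Each population came from mice in which Cre had deleted Mex3a (KO) and from floxed mice without Cre (controls). The 8 footprint libraries form 4 groups of 2, and the deposited table holds 1 column of footprints and 1 column of RNA for each group over coding sequences. Each value is therefore the authors' value for a group with no spread, and the difference between a pair of groups has no replicate check. Intervals in brackets are 95% counting intervals for single genes and receptor sums, and reads copied by PCR without molecular identifiers are not independent molecules. Brackets of list medians, of differences between medians and of correlations are bootstrap intervals over members. Those of matched genes for receptor detection come from sets of matched genes. The columns held 4456989 and 3031489 footprints in Ngn1-GFP control and KO, and 3576406 and 4100841 in OMP-GFP control and KO. RNA totals were 89327877, 27786809, 31855259 and 26946592 in the same order. Gfy, which encodes the Golgi protein goofy of olfactory neurons, had the most footprints in each column, from 2.37% in the Ngn1-GFP control to 3.86% in the OMP-GFP KO. Ratios are log2 of KO over control unless a fold is named, and translational efficiency is the footprint ratio divided by the RNA ratio.

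Mex3a encodes an RNA-binding protein with KH domains and a RING finger, and it was the deleted gene. It had 437 footprints in the Ngn1-GFP control, 28 in the Ngn1-GFP KO, 16 in the OMP-GFP control and 5 in the OMP-GFP KO. Its footprints were 10.1-fold lower in the Ngn1-GFP KO (-3.34 [-3.95, -2.79]) and 3.48-fold lower in the OMP-GFP KO (-1.80 [-3.60, -0.28]). Its RNA counts were 9645, 656, 387 and 38, which gave ratios of -2.25 [-2.37, -2.13] and -3.09 [-3.61, -2.61]. In the controls its footprints were 18.9-fold lower in OMP-GFP than in Ngn1-GFP cells. The gene lies on chromosome 3, 88531946 to 88541394. Counts cover its whole coding sequence, so they do not show where the remaining reads lie relative to the deleted part. Of its relatives, Mex3b footprints were higher in the Ngn1-GFP KO (0.70 [0.26, 1.14]; RNA 0.64 [0.57, 0.71]). In OMP-GFP cells they went from 22 to 0, which gave -2.99 with the 0 set to 3 counts, and the interval bound nearest 0 was -2.57. Mex3b RNA was level there (-0.007 [-0.18, 0.17]). Mex3c was higher in both KO columns (0.54 [0.26, 0.81] and 1.65 [1.24, 2.09]). Mex3d was lower in the Ngn1-GFP KO (-0.88 [-1.53, -0.26]) and had an interval across 0 in OMP-GFP cells (0.71 [-0.55, 2.07]).

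Deletion of Mex3a in Ngn1-GFP cells was read first as a comparison of ribosome footprints in precursors and immature neurons. Footprints of sustentacular cell genes such as the cytochrome P450 Cyp2g1 were far lower in the KO column. The control footprint column stood apart here: 23 genes were at least 8-fold above each other footprint column, against 1, 0 and 0 in the others. Cyp2g1, Sec14l3 and Mex3a were among the 23. With 1 column per group, a difference between the sorts cannot be told apart from an effect of the deletion. Clustered protocadherins, which give neurons distinct surface identities, and adhesion genes that sort olfactory axons had higher footprints, and so had summed olfactory receptors. Immature neuron genes stayed near 0 as a group. Mature neuron genes were slightly higher, with a median of 0.15 (bootstrap interval 0.07 to 0.20), close to the 0.18 of receptors. Among random lists of like abundance, however, the mature neuron median lay at percentile 74.0 and that of receptors at percentile 100. Single members such as the stathmin Stmn4 (higher) and the receptor transport gene Reep6 (lower) differed more. Histone footprints were level while their RNA was far lower, a difference that rests on a control RNA column described below as standing apart.

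Of 12554 genes measured, 815 had at least 2-fold higher and 1361 at least 2-fold lower footprints with a counting interval that excluded 1. The numbers were 198 and 368 with at least 50 counts in 2 columns, and 213 and 439 with at least 100 counts in the pair. RNA of 119 of 806 of the higher genes and 250 of 1355 of the lower genes was also at least 2-fold apart in the same direction. In RNA, 728 genes were higher and 1827 lower. Across genes, which are not independent replicates, footprint and RNA ratios had Pearson's r of 0.263. Spread exceeded counting error at every depth: genes with a mean of 10 to 30 footprints had an SD of 1.63 where counting alone gave 0.54. At a mean of 1000 or more the SD was 0.44 against 0.053, so counting intervals of abundant genes are far narrower than the spread across genes.

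Among genes with a mean of at least 5 CPM (scaled counts), the largest higher footprint ratio was that of Htr6, which encodes a serotonin receptor. It went from 0 to 519 footprints, at least 266-fold, with 0 footprints in both OMP-GFP columns. Its RNA count was 0 in both Ngn1-GFP columns, so the origin of these footprints is uncertain. Rnf135, a RING-finger ubiquitin ligase of antiviral signalling, had 1 and 19 footprints (4.87 [2.22, 10.25]). Piwil2, a piRNA-binding protein, and Timm9, a mitochondrial import chaperone, were higher in footprints (3.27 [2.18, 4.55] and 3.24 [2.15, 4.53]) with RNA ratios of -0.02 and 0.00. The receptors Olfr695, Olfr1457 and Olfr982 were higher (4.17, 4.11 and 3.04), and Olfr1335 and Olfr692 went from 0 to 23 and from 1 to 33 footprints. Reads of single receptors are uncertain where near copies exist.

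Atp6v0a4, a proton pump subunit of ion-transporting epithelial cells, had the largest lower ratio (-5.85 [-8.91, -3.98]; RNA -1.89). Gldn, which encodes the adhesion protein gliomedin, was lower in footprints (-5.11 [-6.57, -3.98]) and RNA (-3.81). Krt19, a keratin of epithelial cells, went from 129 to 0 footprints, at least 27.9-fold. The Wnt receptor gene Fzd6 and the splicing-linked gene Snurf had 1 footprint left of 66 and 52, with RNA ratios of -0.33 and -0.28. Olfr945 went from 98 to 2 (-4.99 [-8.06, -3.10]), and the tubulin gene Tuba1c from 43 to 1. The RNA ratio of Tuba1c was -9.31. Its RNA counts were 160629 in the Ngn1-GFP control, 82 in its KO, and 98 and 189 in OMP-GFP control and KO. That ratio thus rests on the Ngn1-GFP control RNA column, described below as standing apart.

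Sustentacular cells support and detoxify the epithelium. 17 of 23 of their markers were at least 2-fold lower and 1 higher, with a median of -2.27, below each of 10000 random lists of like abundance (RNA -1.36). Cyp2g1 went from 10521 to 468 footprints, 14.6-fold lower (-3.87; RNA -3.34), the lipid-binding gene Sec14l3 had -3.71 [-3.92, -3.50] (RNA -2.94), and the aldehyde dehydrogenase Aldh1a7 had -4.57 [-6.04, -3.43]. Markers of other cells went both ways. Of 17 gland genes 4 were higher and 2 lower (median 0.43, RNA -0.20): the secreted lipid-binding genes Bpifb4 (1.76 [1.61, 1.91]; RNA 1.99) and Bpifb5 (0 to 32) were higher and the mucin Muc5ac lower (24 to 0). Among microvillar and tuft cell genes the keratin Krt18 was lower (-2.18 [-2.56, -1.82]) and the chloride channel Cftr higher (1.32 [0.74, 1.91]), with a list median of 0.16. The collagen gene Col3a1 of connective tissue was higher (1.15 [0.98, 1.33]; RNA 1.37) and the endothelial cadherin Cdh5 lower (-2.60 [-4.96, -0.91]), with a median of -0.07 for vessel and mesenchyme genes. Immune genes had a median of -0.78 over 11 genes (Cd74 -2.68, Ptprc 2.79), ensheathing glia genes 0.19 over 10 (Frzb 3.43, Aldh1a1 -1.08) and horizontal basal cell genes -0.12 over 11, with the basal cell regulator Trp63 at 0.92 [0.55, 1.29].

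Clustered protocadherins had a footprint median of 0.52, above all random lists, and an RNA median of 0.30. Footprints of 48 of 58 were higher, 5 of them at least 2-fold, including Pcdhb11 (1.42 [0.97, 1.88]), Pcdhb19 (1.15 [0.82, 1.49]) and Pcdhga2 (1.00 [0.79, 1.20]). Adhesion genes of olfactory axon sorting had a median of 0.28, at percentile 99.9 of random lists, with 25 of 33 above 0. Among them the teneurin Tenm4 (1.08 [0.93, 1.23]) and the contactin Cntn4 (0.67 [0.63, 0.71]) were higher and the phosphatase Ptprd was lower (-1.27 [-1.82, -0.76]). Axon guidance genes had a median of 0.18, with 33 of 50 higher, yet the ephrin Efnb1 (47 to 2 footprints, -3.93) and its receptors Ephb1 (-2.96) and Ephb3 (-1.79) were lower. Division genes had a footprint median of 0.30 at percentile 99.1 and an RNA median of 0.02. The mitotic kinases Aurkb (2.21 [1.37, 3.12]) and Bub1 (1.84 [0.93, 2.82]) were higher, and the nucleotide synthesis gene Tyms was lower (-2.58 [-3.76, -1.59]).

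Neuronal precursor genes had a footprint median of 0.02 over 22 genes. Their RNA median was 0.29 (bootstrap interval 0.21 to 0.34) over 25 genes, with 19 above 0, at percentile 100 of random lists. Tex15, a chromatin-silencing gene also active in germ cells, was higher (1.04 [0.94, 1.14]), as was the topoisomerase Top2a (0.65 [0.48, 0.82]), while the stem cell factor Sox2 was lower (-1.62 [-2.28, -1.02]; RNA -1.19). Immature neuron genes had a median of 0.04, with Stmn4 (0.89 [0.80, 0.98]) and the RNA-binding gene Elavl4 (0.49) higher and Elavl3 lower (-0.49 [-0.61, -0.37]). Mature neuron genes had a median of 0.15 with 25 of 34 above 0. Umodl1 of mature neurons was higher (0.53 [0.48, 0.57]), and Reep6 (-1.79 [-2.47, -1.16]) and the G-protein regulator Rgs11 (-1.24 [-1.66, -0.84]) were lower. Odour-activity genes had a median of -0.08, with the immediate early genes Nr4a1 (-1.46) and Junb (-0.66) lower. Stress-response genes had a median of 0.15, with Atf5, a factor of the receptor feedback signal, higher (0.64 [0.59, 0.69]) and Atf3 (-1.09) and Psat1 (-2.11) lower. Zonal genes had a median of -0.28, with a bootstrap interval of -0.45 to 0.06, 10 of 17 below 0 and an RNA median of 0.10, with the antimicrobial lectin Reg3g lower (-0.59) and the guidance receptor Nrp1 higher (0.50 [0.37, 0.64]).

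Receptor choice and chromatin genes had a median of 0.09 (Wapl 0.59, Smchd1 0.41), mRNA silencing genes 0.06 (Zfp36l1 -1.92 [-2.40, -1.48], Cnot9 -1.23), and translation factors 0.05 (Eif4e -1.35, Gspt1 0.55). Cilium genes had 0.02, with the motor Dync2h1 (2.07-fold) and the transition zone gene Cep290 (0.96) higher. Synapse genes had 0.10 (Vamp1 1.78, Syt4 -0.46) and p53 and death genes 0.21 (Gtse1 2.15, Bcl2l11 1.47). Trace amine receptors had 0.09 over 10 genes (Taar3 -2.04, Taar7d 1.24), and 1 vomeronasal receptor was measured (Vmn1r84 -0.08).

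The Ngn1-GFP control RNA column stood apart from the other 3: 363 genes were at least 8-fold above each other RNA column there and held 4.86% of its counts, against 2, 0 and 3 such genes in the others. The tubulin Tuba1b had RNA counts of 199783, 123, 40 and 44, and the histone Hist1h4m 17265 and 3 times 0. Actb, Gnai3 and Map1b were not of this kind. Histone footprints had a median of 0.05 in the KO over 62 genes while histone RNA had -1.81 over 76 (Hist1h2ah 1.90 in footprints, -3.38 in RNA), ribosomal protein genes had -0.19 over 44 and -0.89 over 82 (Rpl34 -4.84 in footprints), and mitochondrial genes 0.02 over 7 and -1.13 over 13, so the paired medians cover unlike sets. Translational efficiency, at least 2-fold apart in 2207 of 12530 genes (1001 higher, 1206 lower), rested on this column; its list medians, over genes measured in both, were 1.21 for histones, 0.27 for ribosomal proteins, 0.39 for mitochondrial genes, 0.32 for division genes and -0.55 for sustentacular genes.

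**Figure D1:**
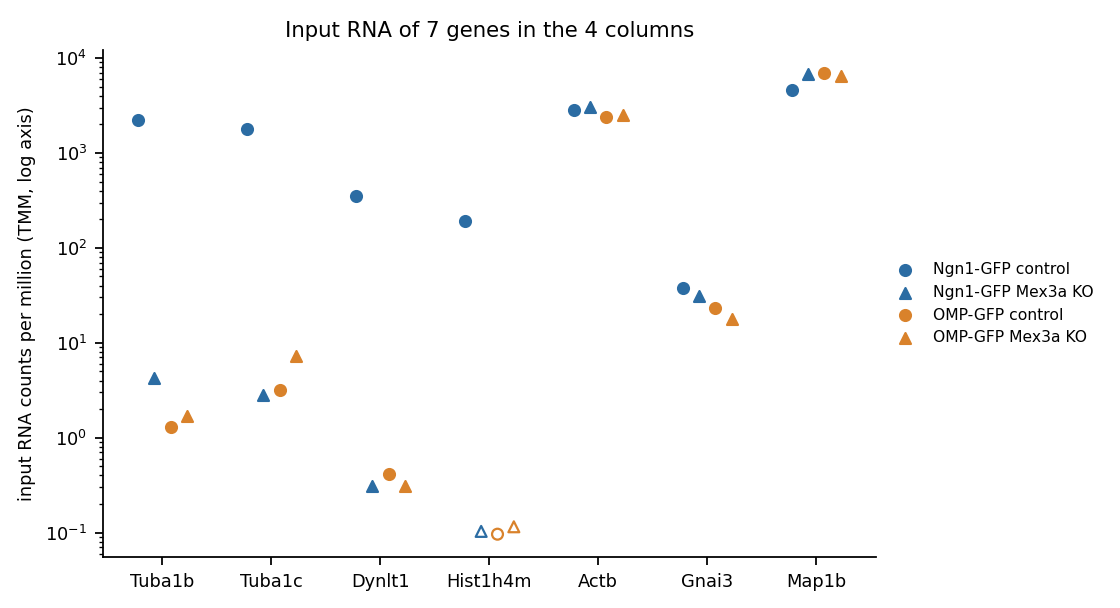
Input RNA of 7 genes in the 4 columns, in TMM-scaled CPM on a log axis. Open markers are counts of 0 drawn at 3 counts; Tuba1b, Tuba1c, Dynlt1 and Hist1h4m stand high in the Ngn1-GFP control alone, and Actb, Gnai3 and Map1b do not.

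The OMP-GFP comparison asked which footprints differed between the KO and control columns of these sorted cells. Secreted proteins of nasal glands, such as the odorant-binding protein Obp1a, and markers of sustentacular cells were far higher in the KO column, in footprints and RNA alike. These are markers of other cells, so the comparison does not describe mature neurons alone. Here too a difference between the sorts cannot be told apart from an effect of the deletion. Immature neuron genes had a lower footprint median with a level RNA median, Gng8 of this list, which encodes a G-protein subunit, had lower footprints with higher RNA, and mitochondrially encoded genes had lower footprints with slightly higher RNA. The immediate early genes Egr1 and Fos, which follow odour activity, were lower, and clustered protocadherins were higher as a group, though only 1 of 58 by at least 2-fold.

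Of 11160 genes, 795 had at least 2-fold higher and 953 at least 2-fold lower footprints. The split was 281 and 271 with at least 100 counts in the pair, and 704 and 1079 by library size alone. RNA was also 2-fold apart in the same direction for 107 of 772 and 54 of 950 of these. RNA differed by that measure in 632 higher and 558 lower genes. Footprint and RNA ratios had r of 0.236 across genes. At a mean of 10 to 30 footprints the SD was 1.56, against 0.52 from counting, and at 1000 or more it was 0.33 against 0.051.

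The largest higher ratios belonged to the pheromone carrier Mup4 (1 to 87 footprints, 6.32 [3.81, 11.64]; RNA 5.90) and Bpifb9b of glands (5.66 [4.28, 7.55]; RNA 4.79). Dmbt1, a mucosal defence protein, had 4.92 [2.35, 10.27] (RNA 3.58), and Tsku, a secreted Wnt and TGF-beta binder, had 4.95 [3.04, 8.02] (RNA 2.57). Each of the mitotic ubiquitin gene Ube2c (5.13), the protease inhibitor Serpina3n (4.79), the actin-binding Cnn2 (4.69) and the chloride channel Clcn2 (4.52) had 1 footprint in the control. At the lower end the cilium gene Spag16 (-5.29), the collagen Col6a1 (-5.12), the sterol regulator Insig1 (-4.87), the ubiquitin ligase Neurl1b (-4.70), the lipid synthesis gene Chpt1 (-4.64) and the secreted Igfbp7 (-4.58) each had 1 footprint left, with RNA ratios between -0.41 and 0.51. The phosphatase Pdxp had -4.87 [-7.96, -2.95], and the receptor Olfr183 went from 76 to 3 (-4.78 [-7.09, -3.18]) with RNA at -4.24.

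Gland genes had a median of 2.71, with 10 of 15 at least 2-fold higher and none lower (RNA 2.80). Obp1a was 15.5-fold higher (3.95 [3.53, 4.40]; RNA 4.37), and the iron-binding Ltf had 3.36 [2.96, 3.79]. Sustentacular markers had a median of 1.43 (RNA 1.30); all 16 were above 0 and 10 at least 2-fold higher, including Cyp2f2 (3.15 [2.77, 3.56]), Ces1d (2.38 [1.85, 2.95]) and Cyp2g1 (3.99-fold). Vessel and mesenchyme genes had 0.79 (0.105 over members with at least 50 counts in 2 columns), with the haemoglobin Hba-a1 of red cells (1.78 [1.40, 2.17]) and the proteoglycan Dcn (1.91 [1.24, 2.64]) higher. Glia genes had 0.31 (Ptn 0.66), tuft cell genes 0.35 (Dclk1 -0.89), immune genes 0.10 (Csf1r -1.52), and the 2 basal cell genes measured 0.35.

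**Figure D2:**
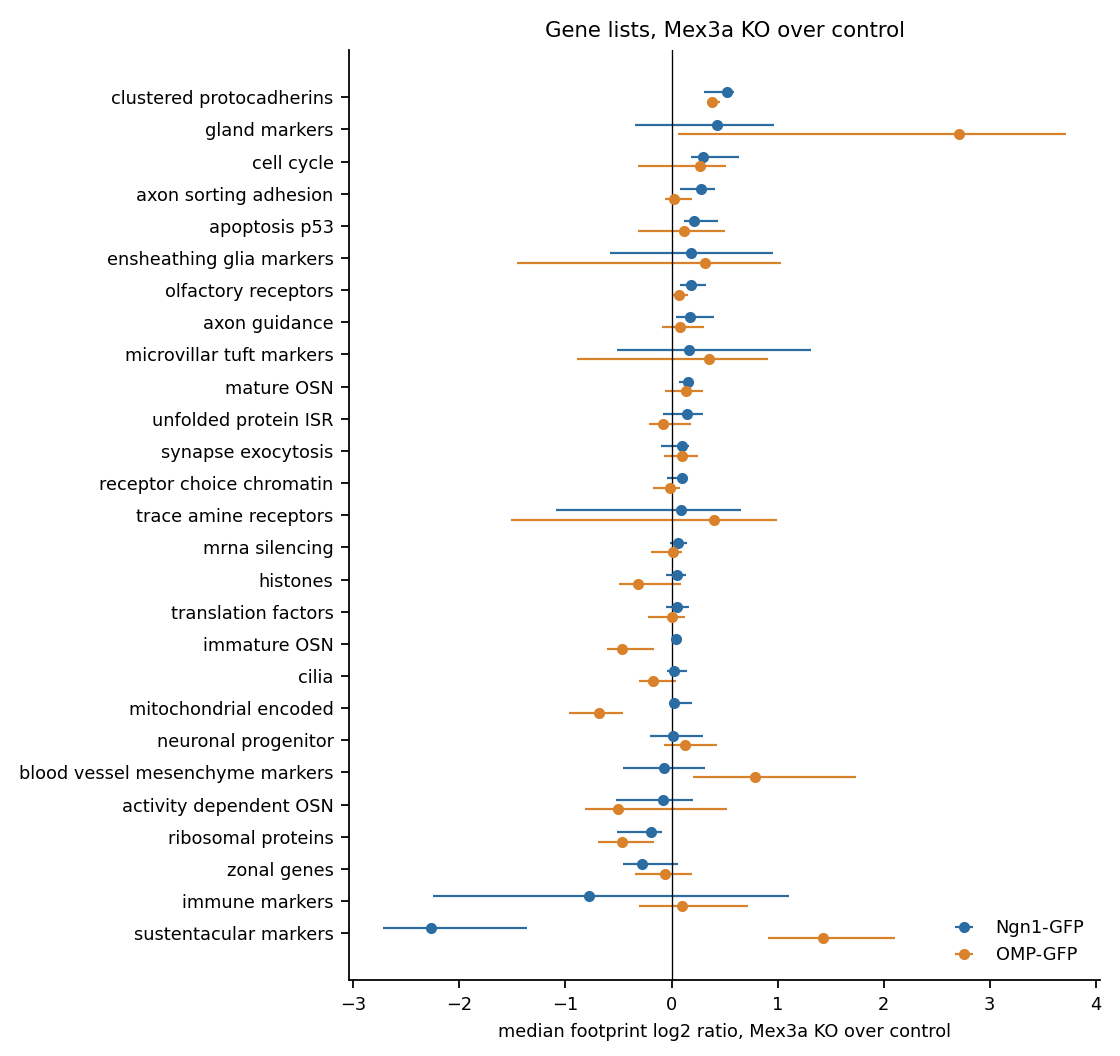
Median footprint log2 ratio of KO over control for gene lists with an interval in both populations, Ngn1-GFP in blue and OMP-GFP in orange. Bars are bootstrap intervals over list members; sustentacular markers lie at -2.27 in Ngn1-GFP and 1.43 in OMP-GFP cells, and gland markers at 2.71 in OMP-GFP cells.

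Immature neuron genes had a footprint median of -0.47, below all random lists, and an RNA median of 0.02. Gng8 (-1.04 [-1.41, -0.67]; RNA 0.46), the actin-binding Dbn1 (-0.91 [-1.17, -0.65]; RNA -0.02) and the growth cone gene Basp1 (-0.87 [-1.16, -0.59]; RNA 0.04) were lower. All 7 mitochondrial genes were lower (median -0.69, RNA 0.18), among them mt-Co1 (-1.45 [-1.54, -1.36]) and mt-Nd5 (-0.93 [-1.02, -0.84]). Ribosomal protein genes had -0.47 (RNA 0.06), with 30 of 41 lower, such as Rpl41 (-2.22 [-2.76, -1.72]), and Rpl30 higher (4.05 [2.43, 6.37]). Egr1 (-1.88 [-2.16, -1.60]) and Fos (-1.48 [-1.68, -1.27]; RNA -0.72) led the odour-activity list (median -0.51). Atf3 (-2.16) and Trib3 (-1.23) were lower and Atf5 was higher (0.56 [0.49, 0.63]) in a stress list with a median of -0.08. Histones had -0.31, although the linker histone Hist1h1e was higher (2.20-fold). Translational efficiency was at least 2-fold apart in 1774 of 11124 genes (789 higher, 985 lower), with medians of -0.47 for immature neuron genes and -0.78 for mitochondrial genes.

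Protocadherins had a median of 0.38, above all random lists, with 49 of 58 higher (RNA 0.11). By the 2-fold measure 1 was higher and 3 were lower. Pcdhb21 (-2.89), Pcdhb3 (-2.25) and Pcdhb2 (-2.12) were lower. Mature neuron genes had 0.14, with the synaptic Snap25 higher (0.78 [0.68, 0.87]) and Reep6 (-1.75) and Rgs11 (-1.07) lower, as in Ngn1-GFP cells. The looping factor Ctcf (0.74 [0.59, 0.89]) and the heterochromatin gene Cbx1 (0.69) were higher in a receptor choice list at -0.01. Axon guidance genes had 0.08 (Efna3 -0.59, Plxna2 1.93) and axon sorting genes 0.02 (Cntn1 -1.26, Tenm1 -1.89). Precursor genes had 0.13 (Gadd45g 3.01), division genes 0.27 (Tpx2 2.25, Mki67 1.98, Pcna -1.53), zonal genes -0.06 (Cyp26b1 -0.97), silencing genes 0.02 (Zfp36 -3.09, Pan3 -1.94) and translation factors 0.00 (Eif4ebp1 -3.70, Eif4e 1.44). Cilium genes had -0.17 (Bbs10 1.49, Cep290 0.84), synapse genes 0.10 (Cacna1a -2.93), death genes 0.11 (Mdm2 0.98, Trp53inp1 -2.19), trace amine receptors 0.40 (Taar6 1.46 [1.19, 1.73], Taar9 -2.37, Taar5 -2.84), and the vomeronasal Vmn2r2 had -0.12.

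Olfactory receptors, of which each mature neuron expresses 1 allele, held 0.833% of footprints in the Ngn1-GFP control, 0.903% in its KO, 0.962% in the OMP-GFP control and 0.95% in its KO. In Ngn1-GFP cells their summed footprints were 1.14-fold [1.12, 1.15] higher and their summed RNA was 0.889-fold [0.883, 0.895] of the control. Footprints per RNA read were thus 1.28-fold [1.26, 1.30] higher, at 1.14 [1.09, 1.19] for class I and 1.29 [1.27, 1.32] for class II receptors. In OMP-GFP cells the sums were 1.04-fold [1.03, 1.06] for footprints (0.987-fold by library size alone), 1.09-fold [1.08, 1.10] for RNA and 0.954-fold [0.938, 0.969] for the ratio. The footprint median over receptors was 0.18 in the Ngn1-GFP KO, with 147 of 720 at least 2-fold higher and 120 lower. In the OMP-GFP KO the median was 0.07, with 110 of 716 higher and 108 lower, and it was -0.0111 by library size alone and -0.0346 without a filter.

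Fewer receptors carried footprints in both KO columns at equal numbers of receptor footprints. After thinning to 27378 footprints, 1004 receptors were detected in the Ngn1-GFP control and 900 in its KO, and 999 and 884 in OMP-GFP cells. The effective number of receptors was 590 and 551 in Ngn1-GFP and 581 and 527 in OMP-GFP cells, and in RNA 780 and 710, then 715 and 685. Other genes of the same abundance were also detected less often: detection of receptors differed by -9.34 percentage points and of matched genes by -5.75 [-7.86, -3.74] in Ngn1-GFP cells, against -10.8 and -11.3 [-13.8, -8.27] in OMP-GFP cells. In RNA the values were -1.41 and -2.98 [-4.31, -1.63] in Ngn1-GFP and -1.65 and -1.48 [-2.72, -0.22] in OMP-GFP cells. Olfr1507, the receptor with the most footprints in both controls, had 693, 108, 646 and 155 footprints. Olfr536 had 515, 221, 549 and 288, whereas Olfr19 had 269, 269, 181 and 278.

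The differences between KO and control columns in Ngn1-GFP and OMP-GFP cells, called effects below, were compared gene by gene. The support cell gene Cyp2g1 and the secreted Tsku went in opposite directions in the pair of populations. Some single receptors differed in the same direction, for example Olfr1507 and Olfr1280, and among other genes Gucy1b2, the guanylate cyclase subunit of hypoxia-sensing neurons, did so too.

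Footprint ratios of the populations were almost unrelated over all 10845 genes (r 0.0502), and r was 0.253 [0.18, 0.33] over 622 receptors and 0.0213 over other genes. In RNA, r was 0.413 [0.34, 0.48] over 1012 receptors and -0.0397 over other genes; these brackets are bootstrap intervals. By rank the contrast was smaller, with Spearman rho of 0.325 over receptors and 0.0804 over other genes in RNA, and 0.260 and 0.0590 in footprints. Genes with a mean of at least 100 footprints had a rho of 0.230 in RNA, with r of -0.0776. Footprints of 91 genes were 2-fold higher in both KO columns, where independent lists would share 30.3, and of 157 genes lower in both, against 76.8. Genes lower in Ngn1-GFP and higher in OMP-GFP cells numbered 120, against 57.3, and the reverse 56, against 40.6. Opposite directions thus exceeded independent lists as well. Spread was larger among genes with few footprints in both populations, so the same genes can be called in both more often. The excess alone therefore shows no agreement. The difference of the effects (OMP-GFP minus Ngn1-GFP) was at least 2-fold in 2381 genes, 1230 higher and 1151 lower. It was 1403 genes with at least 50 counts in 2 columns and 944 with at least 100 counts in the pair. For Tsku it was 8.29 [6.21, 10.37], for Gldn 7.05 [5.32, 8.79], for Cyp2g1 5.86 [5.61, 6.12], for the transporter Abca13 5.50 [4.73, 6.27] and for Cyp2f2 5.37 [4.96, 5.77]. Lower differences were those of Neurl1b (-6.65), Col6a1 (-6.06), Olfr1226 (-4.94), the RNA-binding Ralyl (-4.30) and Smim19 (-4.18). Sustentacular genes had a median difference of 3.84 (13 of 16 at least 2-fold), gland genes 2.60, vessel genes 1.06, mitochondrial genes -0.68, immature neuron genes -0.27 and receptors -0.16. For Mex3a the difference was 1.54 [-0.01, 3.09].

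**Figure D3:**
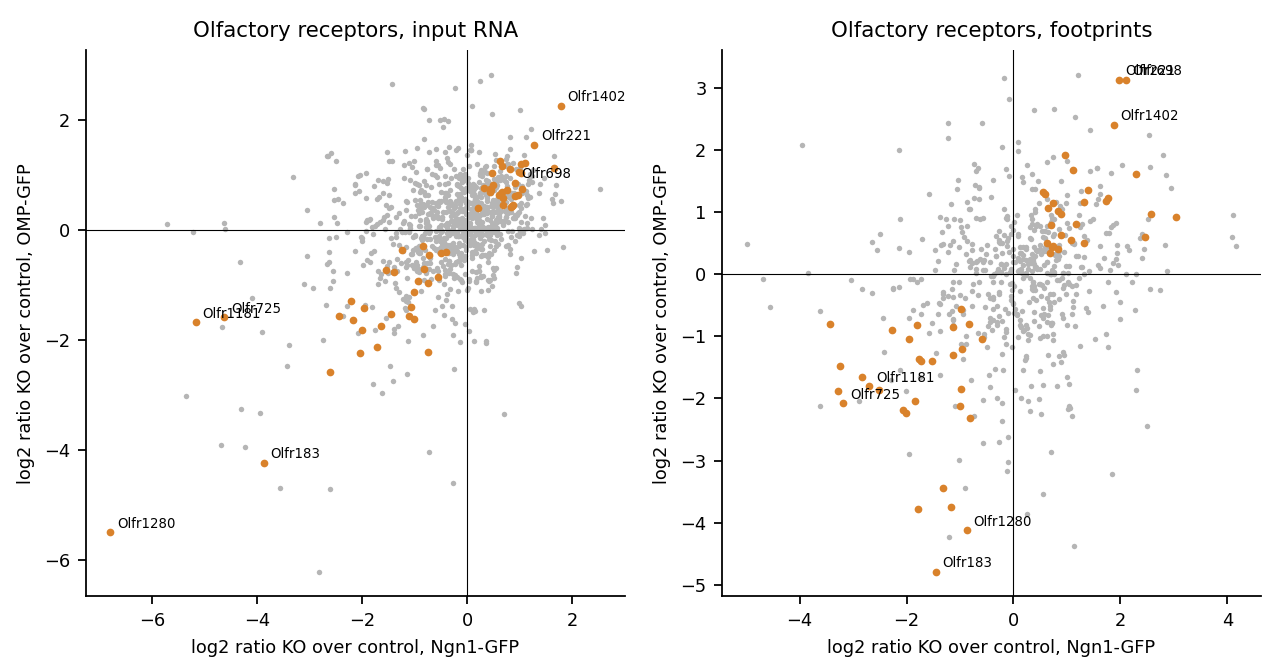
Log2 ratio of KO over control of each olfactory receptor in Ngn1-GFP (horizontal) and OMP-GFP (vertical) cells, RNA on the left and footprints on the right. Orange points are receptors with counting intervals on the same side of 0 in all 4 column pairs (30 lower, 29 higher); r was 0.413 in RNA and 0.253 in footprints.

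OMP-GFP cells were compared with Ngn1-GFP cells, first in the controls. Precursor genes such as Neurog1 and Neurod1, division genes, and markers of basal, support, gland and connective tissue cells were far lower in OMP-GFP cells. Mature neuron genes such as Ano2, the chloride channel of olfactory transduction, and genes of cilia, synapses and receptors were higher. The same lists led in the KO pair, except that support and gland markers differed much less there. Since markers of support, gland and connective tissue cells are among the genes counted, the numbers do not describe maturation of neurons alone.

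In the controls 757 of 12387 genes were at least 2-fold higher and 2160 lower in OMP-GFP cells, so that 26.0% of them were higher; scaling by library size alone gave 15%. With at least 50 counts in 2 columns 398 were higher and 792 lower, and with at least 100 counts in the pair 374 and 853. Footprint and RNA ratios had r of 0.712. Precursor genes had a median of -2.71, with 17 of 22 at least 2-fold lower, including Neurog1 (-5.65 [-6.97, -4.60]) and Neurod1 (-4.35 [-4.86, -3.88]). Division genes had -2.04 (Mki67 -3.48, Tpx2 -3.89, Cenpe -3.96), basal cell genes -3.48 (Krt5 -5.58 [-7.21, -4.34]), histones -1.31 (Hist1h2ab -3.86) and immature neuron genes -0.92 (Ablim1 -2.27 [-2.84, -1.74]). Mature neuron genes had 0.78, with Umodl1 (1.61 [1.57, 1.65]), the lipid droplet gene Cidea (1.68 [1.44, 1.93]) and Ano2 (1.24 [1.16, 1.32]) higher. Cilium genes had 0.49 (Ift172 1.43, Dync2h1 1.38, Bbs5 1.23), synapse genes 0.58 (Slc17a6 0.98), axon sorting genes 0.38 (Pcdh8 1.39 [1.26, 1.53]), protocadherins 0.37 (Pcdhb13 2.58) and trace amine receptors 0.74 (Taar9 2.24). Odour-activity genes had 0.02, with Kirrel2 (1.20 [1.13, 1.26]) and Pcp4l1 (1.34 [1.23, 1.45]) higher. Receptors had 0.43, with 181 of 765 higher and 62 lower, and their sums were 1.34-fold higher in footprints and 1.10-fold in RNA. By library size alone the medians were 0.567 for mature neuron genes, 0.277 for cilium genes, 0.218 for receptors and 0.154 for protocadherins. The receptor choice factors Lhx2 (-1.75 [-1.92, -1.59]; RNA -0.29) and Tshz1 (-2.30 [-2.67, -1.95]; RNA -0.77) were lower in footprints.

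Largest of all in the controls were Tsku (-7.75 [-10.80, -5.89]), Cnn2 (-7.42), the actin regulator Cap2 (-7.05), the sugar transporter Slc5a1 (-7.02), Atp6v0a4 (-6.94) and Hist1h4m (478 to 0, at least 110-fold lower). Ifitm3 of antiviral defence (-6.76) and Krt19 (-6.48) followed. On the higher side Lrriq4 (5.74), Rnf135 (5.44) and Olfr136 (5.12) each had 1 footprint in Ngn1-GFP cells. Sustentacular genes had -4.58, with 22 of 23 lower (Cyp2g1 -5.18 [-5.39, -4.98], Muc2 -5.71), gland genes -2.68 (Ltf -3.02), glia genes -2.17 (Sparc -3.33), vessel and mesenchyme genes -3.01 (Col1a1 -3.02) and tuft cell genes -1.71 (Krt18 -3.96).

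In the KO pair 1325 of 11766 genes were higher and 2162 lower in OMP-GFP cells, 38.0% higher, or 25.9% by library size alone. With at least 50 counts in 2 columns 731 were higher and 1052 lower, and with at least 100 counts in the pair 646 and 761. Lower genes included Col6a1 (-8.02), Htr6 (519 to 0), the growth factor binder Igfbp2 (349 to 0), the proteoglycan Bgn (260 to 0) and Neurog1 (-6.71 [-9.00, -5.15]). Tuba1c (6.48), Olfr945 (5.77 [3.88, 8.83]) and Fzd6 (5.70) were higher. Precursor genes had -2.57 (Cxcr4 -4.36), division genes -1.95, basal cell genes -4.48 (Krt5 -6.31), immature neuron genes -1.23 (Gng8 -3.14 [-3.46, -2.83], Dbn1 -2.51 [-2.74, -2.29]) and histones -2.06. Mature neuron genes had 0.80 (Pde1c 2.84-fold, Cidea 1.78, Kcnmb3 1.73), cilium genes 0.31 (Kif3a 1.12 [1.03, 1.21]), synapse genes 0.46 (Snap25 1.20), receptors 0.33 and trace amine receptors 1.32 (Taar6 2.48 [2.12, 2.86]). Sustentacular genes had -0.63, with 8 of 20 lower (Scgb1c1 -3.19), and gland genes -0.49 (Muc5b -4.44).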

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

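Of the tests in this part, the one on receptor families in RNA, the one without the 5 most abundant receptors and the one on small receptor families across populations were written before their values were seen; the others were chosen after the result was seen.

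The differences between populations that stood out most were not tested. Sustentacular genes had a median footprint ratio of KO over control of -2.27 in Ngn1-GFP and 1.43 in OMP-GFP cells, 3.70 apart. Dmbt1, a mucosal defence gene, had -0.74 and 4.92, 5.67 apart. Gldn, the gliomedin gene, had -5.11 and 1.94, 7.05 apart. Tsku, a secreted signalling modulator, had -3.34 and 4.95, 8.29 apart.

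Tuba1b, histones and other genes, 363 in all, stood at least 8-fold above the other RNA columns in the Ngn1-GFP control. Reads shared between near-identical copies may have been counted in that column and dropped in the other 3: with histones and receptors left out, 51.3% of 154 members (79) had a neighbour of the same symbol start, against 11.1% on average and percentile 100 of random sets. This test was the last of 3 versions; the first asked whether genes with a named pseudogene stood low in Ngn1-GFP KO RNA and level in OMP-GFP RNA, and gave -0.51 at percentile 0 and 0.04 at percentile 99.96, which did not meet its own terms, and the next matched on footprints and gave 48.3% of 29 against 14.4%. A loss of these RNAs through Mex3a deletion, with footprints following, was checked over the 40 members with footprints measured. Their RNA median was -4.08 [-4.63, -3.42] and their footprint median -0.17 [-0.70, 0.20]. Members had been chosen for RNA at least 8-fold above each other column, so the RNA median and the bound taken from it were low by that choice. Footprints were not used in the choice. They did not fall as far as the RNA, a gap that the choice sets in part. A smaller loss, an offset by translation and the members without enough footprints stayed open. This test was also the last of 3 versions, and its bound was changed after the values were seen; under the bound used before, a footprint interval above -0.5, the loss had been left open. More dividing cells in the control did not account for it, since RNA of the division list had a median of 0.0192 [-0.02, 0.16].

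Receptor messages summed over all receptors had 1.28-fold more footprints per RNA read in the Ngn1-GFP KO. The scaling of columns did not remove this for the sum of all receptors, with ratios from 1.17 to 1.29 over 4 scalings, but by library size class I receptors had 1.047 [1.004, 1.092] and small families 1.061, so for these the scaling stayed open. A few abundant receptors such as Olfr1507 did not set the sum, which was 1.30 without the 5 most abundant. Reads shared between receptor copies and counted in the control RNA alone remained possible: receptors of large families (479) minus those of small ones (240) had a difference of -0.10 [-0.34, 0.08] in median RNA ratio, which did not separate the cases. The control RNA column that stood apart enters this ratio, so it could likewise carry part of it.

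The same receptors, such as Olfr1507 and Olfr1280, stood low or high in the KO columns of both populations. Over 10000 shuffles of the receptors r was at most 0.115, against 0.413 in RNA. The shuffles treat receptors as independent, yet RNA ratios of next neighbours had r of 0.299 in Ngn1-GFP and 0.229 in OMP-GFP cells. With 1 column per group they cannot address chance between animals, so chance of that kind stayed open. Shared reads between copies did not account for the agreement among 232 receptors of small families, where r was 0.398 [0.24, 0.53]. Fewer neurons of the ventral zone in the KO columns was left open. The median RNA ratio of the ventral genes Ncam2, Nfia, Nfib and Nfix minus that of the dorsal genes Nqo1 and Acsm4 was -0.17 in Ngn1-GFP and -0.17 in OMP-GFP cells, short of the 0.2 required. Single genes were mixed in RNA. In Ngn1-GFP cells Ncam2 (0.005), Nfib (-0.053) and Nfix (0.131) lay above Acsm4 (-0.095), and Nfia (-0.385) lay below. In OMP-GFP cells Nfib (-0.004) and Nfix (0.090) lay above Acsm4 (-0.019), and Ncam2 and Nfia lay below. Nqo1 was the highest of these genes in both (0.397 and 0.204). The required difference was set for RNA alone. In footprints the ventral genes were all below 0 in Ngn1-GFP and OMP-GFP cells. Ncam2 had -0.126 and -0.323, Nfia -0.278 and -0.395, Nfib -0.470 and -0.481, and Nfix -0.395 and -0.341. Of the dorsal genes Nqo1 had 0.064 and 0.072 and Acsm4 -0.326 and -0.060, so Ncam2 and Nfia lay above Acsm4 in Ngn1-GFP cells. The groups differ by animals as well as by genotype, and sex, litter or genetic background of the animals stays open as untested.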

How the results depend on the processing

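Alternatives fixed before the data were examined were scalings and filters for the gene comparisons and their named genes, DESeq2 size factors for lists, the filter of 50 counts for the agreement of effects, 3 counts as detection, and DESeq2 size factors, library size and removal of the 5 most abundant receptors for summed footprints. All others were chosen after the data were seen, among them every alternative for efficiency and for receptor RNA, other scalings and filters for lists, 0.5 added to counts, at least 100 counts in the pair, and removal of histones and genes with named pseudogenes. A number of genes was taken as the same within 1.5-fold of the main value, and any other value inside the main interval, which is narrow for receptor sums. Of the main results 73 values stayed the same, 29 moved and 1 reversed, and of the others 829 stayed, 9 moved and 3 reversed.

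Numbers of genes at least 2-fold apart depended on the filter, which sets how many genes are tested. Without a filter beyond 1 count they were 2907 for the Ngn1-GFP KO, 2558 for the OMP-GFP KO, 2763 for the difference of effects, 3552 for the control populations and 4729 for the KO populations, and 2602 and 2106 for efficiency. With at least 50 counts in 2 columns they were 566 for the Ngn1-GFP KO, 792 for the OMP-GFP KO, 1403 for the difference of effects, 1190 for the control populations and 1783 for the KO populations, and 670 and 840 for efficiency in the Ngn1-GFP and OMP-GFP KO. With at least 100 counts in the pair they were 652, 552, 944, 1227 and 1407, and 740 and 591 for efficiency. Higher and lower genes then numbered 213 and 439 in the Ngn1-GFP KO and 281 and 271 in the OMP-GFP KO, where more genes had been lower (795 and 953).

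Summed receptors in the Ngn1-GFP KO had footprints of 1.08 and RNA of 0.924 by library size, footprints of 1.16 without the 5 most abundant, and efficiency of 1.17 by library size, 1.15 in small families and 1.18 by the authors' scaling. In the OMP-GFP KO the direction of summed footprints reversed by library size (0.987), with 1.06 by DESeq2 size factors and 1.06 without the 5 most abundant. RNA there was 1.10 by DESeq2, 1.08 by library size and 1.10 without the 5, and efficiency 0.915 by library size and 0.927 in small families. With 3 counts as detection, the KO columns had fewer receptors, -69.7 in Ngn1-GFP and -86.1 in OMP-GFP cells, against -104 and -115 with 1 count. Among list medians, receptors in the OMP-GFP KO reversed to -0.0111 by library size and -0.0346 with no filter, and immature neuron genes in the Ngn1-GFP KO to -0.0282 by library size. By library size these medians moved: in the control populations receptors to 0.218, protocadherins to 0.154, mature neuron genes to 0.567, cilium genes to 0.277, mRNA silencing genes to -0.333 and translation factors to -0.211, protocadherins in the OMP-GFP KO to 0.307 and mitochondrial genes in the Ngn1-GFP KO to -0.0433. Vessel genes in the OMP-GFP KO had 0.105 with at least 50 counts. The cause was not tested, apart from the smaller number of genes under stricter filters.

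No paired analysis was possible because the columns carry no replicate number. DESeq2 Wald tests, voom, edgeR without robust fitting, a replicate block, leave-one-out fits, fits on 2 groups, camera and fry set tests, the DESeq2 interaction and permutation tests were not run, since each group has 1 column.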

Other observations

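The test on neighbouring receptors in this part was chosen after the result was seen, when names from chromosomes 14 and 2 recurred.

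Receptors with counting intervals on the same side of 0 in all 4 pairs of KO and control columns numbered 30 lower and 29 higher of 622, and 25 and 13 of these differed by at least 0.5 throughout. Among the lower ones were Olfr1280, Olfr1181, Olfr1183, Olfr1199, Olfr1206, Olfr1211, Olfr1260 and Olfr1264 of chromosome 2, and Olfr725, Olfr726, Olfr727 and Olfr740 of chromosome 14. Higher ones lay on the same chromosomes, Olfr73, Olfr1019, Olfr1102 and Olfr1209 on chromosome 2 and Olfr221 and Olfr734 on chromosome 14, and shares of receptors were not compared between chromosomes. Olfr1507 (chromosome 14, 52489935 to 52495695) had footprint ratios of -2.06 [-2.37, -1.77] and -2.18 [-2.44, -1.92] in Ngn1-GFP and OMP-GFP cells, with RNA at -2.03 and -2.23. Its neighbours were mixed. Olfr1508 was lower (-0.83 and -0.80; RNA -0.84 and -0.30), and Olfr1509 was lower in RNA (-1.11 and -1.21) and had footprint ratios of -1.08 [-1.91, -0.32] and -0.51 [-1.19, 0.15]. Olfr1510 had -1.88 and -0.08 (RNA -0.90 and -0.37) and Olfr1511 had 0.36 [-0.39, 1.10] and -0.38 [-1.01, 0.25] (RNA -1.42 and -0.25). Olfr1512 had 1.73 and 0.66 [-0.35, 1.72] (RNA 0.24 and 0.66) and Olfr1513 had 0.92 and -0.22 (RNA 0.08 and 1.45). Olfr1402, Olfr221 and Olfr698 led the higher receptors, with mean ratios of 2.08, 1.98 and 1.75.

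Other genes on the same side throughout were 80 lower and 219 higher of 10207, and 13 and 17 of these by at least 0.5. Gucy1b2, a guanylate cyclase subunit of hypoxia-sensing olfactory neurons, went from 61 to 0 and from 197 to 46 footprints, with RNA at -1.92 and -2.45. Scgn, which encodes the calcium sensor secretagogin, had -0.61 and -0.66 in footprints and -0.97 and -0.98 in RNA. The RNA helicase Mov10 (-1.03 and -1.76) and the fatty acid carrier Fabp5 (-0.58 and -1.32) were lower, and the adenylate kinase Ak7 of motile cilia (1.55 and 0.91), Stmn4 (0.89 and 0.67), the carbonic anhydrase Car6 (1.06 and 2.72) and the calcium pump Atp2a3 (1.04 and 1.79) were higher.

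Neighbouring receptors may shift together through a difference that acts on whole clusters, such as genetic background or a shared enhancer. Next neighbours within 100 kb that belong to different families had r of 0.353 [0.18, 0.49] over 312 pairs in RNA averaged over both populations, and the highest of 10000 shuffles was 0.25. This was 1 of 12 correlations computed, and the pairs are not independent. Footprints of such pairs had 0.0919, inside the range of shuffles, and those of all next neighbours 0.178 [0.07, 0.30] over 345 pairs with a highest shuffle of 0.175. In single populations footprints of all next neighbours had 0.0213 in Ngn1-GFP and 0.0402 in OMP-GFP cells, inside the range of shuffles. In OMP-GFP RNA alone r was 0.225 with a highest shuffle of 0.268, whereas in Ngn1-GFP RNA alone it was 0.222 with a highest shuffle of 0.197. Sequencing the receptor clusters of the KO and control mice could separate background from deletion.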
